A study of Escherichia coli with 18 samples.

How the data were processed

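RNA was measured in 18 libraries of Escherichia coli MG1655 PCP18-araE in 6 groups, with pBAD24 or pBAD24 carrying symE, at 0, 30 and 90 min of arabinose. Per the labels' protocols, rRNA was subtracted and libraries were random primed and kept strand by dUTP. Bowtie2 and DESeq2 are named in the submitters' processing notes without a version, and the genome build and the counting rule are not given in the sources used here.

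The deposited coverage files hold raw signal, the depth of each of 4639675 positions on 2 strand columns, as whole numbers not scaled to library size. Which column is which strand is not given in the sources used here. The deposited tables of the authors' comparison, 1 for 30 and 1 for 90 min, hold for 4285 genes the log2 fold change, its SE, the Wald score, the p-value and adjusted p-value, and the mean normalized count signal, per the file headers. The sign of the fold change was taken as symE over empty vector because symE had the largest positive value among genes past the test. Of 4285 gene names, 4006 matched current symbols and 4224 matched with synonyms in the reference table of assembly ASM584v2. That reference ends beyond the files' last position (its last gene ends at 4641628), so it was used for names only and no gene was placed on the coverage.

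The design, the gene lists and most alternatives were fixed before the data were examined, with genes as the unit. Since genes could not be placed, segments of 500 nt per strand replaced them, and blocks of 1000 nt replaced genes in the test of local coverage. Depth was scaled to 1000000000 coverage bases per library and then by trimmed mean factors (30% of folds and 5% of levels trimmed) over segments with a mean depth of at least 5. Log2 of depth plus a pseudocount of 1 was fitted with limma 3.58.1 in R 4.3.3 with a trend, over all 18 libraries and 6 groups with 12 residual degrees of freedom. Fold changes on that scale understate the change of weakly covered segments. Tests were two-sided with Benjamini-Hochberg adjustment at 0.05. The effect of symE was compared between times by interaction terms. For local coverage, windows of 50 nt in blocks with a mean depth of at least 20 were compared with the rest of their block, and a loss or gain was a called log2 change of at least 1 in size. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these libraries.

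Gene lists were tested with limma's cameraPR on the authors' deposited Wald score with a preset correlation of 0.01, which compares a list with all other genes. Of 747 genes in the 29 lists, 739 were matched. Estimated correlations, fry and gene lists at 0 min need gene values per library and were not run. Genes were compared between times by the difference of their log2 fold changes over its SE, which takes the times as independent and leaves out the pairing. Adjusted p-values quoted from the authors' deposited table are those of DESeq2. Genes were named by a rule fixed in advance. It took the 10 largest called changes in each direction for symE against empty vector, 5 for other comparisons, 4 members per called list and the 5 strongest local losses, with symE and the ara genes always named. For coverage segments it also required that groups did not overlap, and for the authors' tables it used the adjusted p alone.

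Replicate numbers were treated as pairing the samples in the alternatives with a block and in the counts of splits. The rule was that every pair of same-numbered libraries correlates above 0.1. The fits behind the reported counts hold no term for that pairing. Deviations from group means correlated in each of 9 pairs of same-numbered libraries with different plasmids at the same time (r from 0.128 to 0.933) and in each of 18 pairs of times with the same plasmid (0.399 to 0.894), across segments. Between plasmids the mean r was 0.81 for number 1, 0.32 for number 2 and 0.24 for number 3, and pairs with different numbers reached 0.769. Between plasmids only the 6 libraries of replicate 1 correlated best with their own number. At every time empty vector 2 correlated best with symE 3, and empty vector 3 with symE 2. Those r were 0.742 and 0.769 at 0 min, 0.507 and 0.427 at 30 min, and 0.335 and 0.5385 at 90 min. The values thus go against pairing numbers 2 and 3 between plasmids, and the limit of 0.1 did not tell these pairs apart. Between times with the same plasmid, the own number was best in 34 of 36 comparisons. Replicate 1 was 8.46 to 11.8 times deeper than the mean of replicates 2 and 3 of its group. Its match between plasmids therefore cannot be told apart from depth. No replicates were copies, since 0.312% to 10.2% of covered positions had identical depth.

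Alternatives were median-of-ratios scaling, scaling to the total of tested segments, pseudocounts of 0.1 and 10, no filter and a filter at 50, limma without trend, the replicate number or the culture as a block, the compared groups alone, and each library left out. Windows of 25 and 100 nt, block depths of 5 and 100 and a pseudocount of 5 were tried for local coverage. Replicates 2 and 3 alone, the comparison with both flanks and all alternatives for the lists were added after the data were seen. Simulated data with 200 known changes were used to test the segment comparison of symE with empty vector, at a single time. The same number was placed for windows against their block and for windows against both flanks. Comparisons between times, of segments or of genes, were not tested in this way. The list test was run on 50 rounds of shuffled statistics. There a list shifted by 1.5 was recovered in 98% of rounds, with 5 false calls among 1400. Shuffling removes any correlation between members of a list, so these rates do not cover lists whose members vary together. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the depths and figures.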

Results

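SymE is a small Escherichia coli protein of the SOS (DNA damage) response that resembles a DNA-binding antitoxin, and the series asked whether it cleaves RNA. Strain MG1655 PCP18-araE, which makes the arabinose transporter AraE from a constitutive promoter, carried either the arabinose-inducible plasmid pBAD24 or pBAD24 with symE. Cultures in M9 medium were sampled at OD600 0.5 before induction, and again 30 and 90 min after 0.02% arabinose was added. Each of the 6 combinations of plasmid and time had 3 libraries, 18 in all, of RNA from which rRNA had been subtracted. Each library was given as depth per base on 2 strands over 4639675 positions, and 2 deposited tables gave the authors' comparison of symE with empty vector for 4285 genes at 30 and at 90 min.

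Depth differed by replicate number and not by group. Replicate 1 of every group held 4.86 to 6.51 gigabases of coverage, and replicates 2 and 3 held 0.442 to 0.692 gigabases. A depth of 0 was found at 2.85% to 8.57% of positions in the 6 libraries of replicate 1, against 31.8% to 46.1% in the 12 others. That share also followed induction of symE. In replicate 1 it was 3.36% and 2.85% with symE at 30 and 90 min and 7.36% to 8.57% in the rest. In replicates 2 and 3 it was 31.8% to 37.0% with symE at 30 and 90 min and 38.6% to 46.1% in the rest. Total coverage of these induced libraries was not above the range of the rest. Coverage was more concentrated after induction of symE: the 20000 deepest positions held 68.2% ± 7.61 (SD, n = 3) of coverage in the symE libraries at 30 min and 41.0% ± 1.18 (SD, n = 3) in the empty vector libraries. At 90 min the shares were 52.3% ± 2.31 and 46.2% ± 1.43 (SD, n = 3 each), and at 0 min they were 45.5% ± 2.99 and 43.8% ± 1.28 (SD, n = 3 each).

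The induced gene was examined first. In the authors' deposited table symE was higher by a log2 fold change of 14.69 ± 0.45 (SE, adjusted p = 2.34e-227) at 30 min and of 9.80 ± 0.99 (SE, adjusted p = 1.18e-19) at 90 min. The sign of both tables was itself taken from symE, so only the coverage files check the labels. Of the other genes past the test at 30 min in the authors' deposited table, none exceeded 6.40, the value of ybfL, while ykgM (7.62 ± 2.44, SE) and ykgO (7.34 ± 2.38, SE) had no adjusted p. The coverage files carry no gene names, and no position was matched to a gene, but a single segment showed a change of that size. On strand column 2 from 4577501 to 4578000, normalized depth was 188100 ± 92260 (SD, n = 3) with symE at 30 min and 7.58 ± 0.287 (SD, n = 3) with empty vector, a log2 change of 14.30 ± 0.79 (SE, limma adjusted p = 1.05e-07). At 90 min the log2 change there was 10.67 ± 0.79 (SE, limma adjusted p = 6.65e-06). This segment alone took 8.97%, 5.60% and 4.41% of all coverage in the symE libraries at 30 min.

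**Figure D1:**
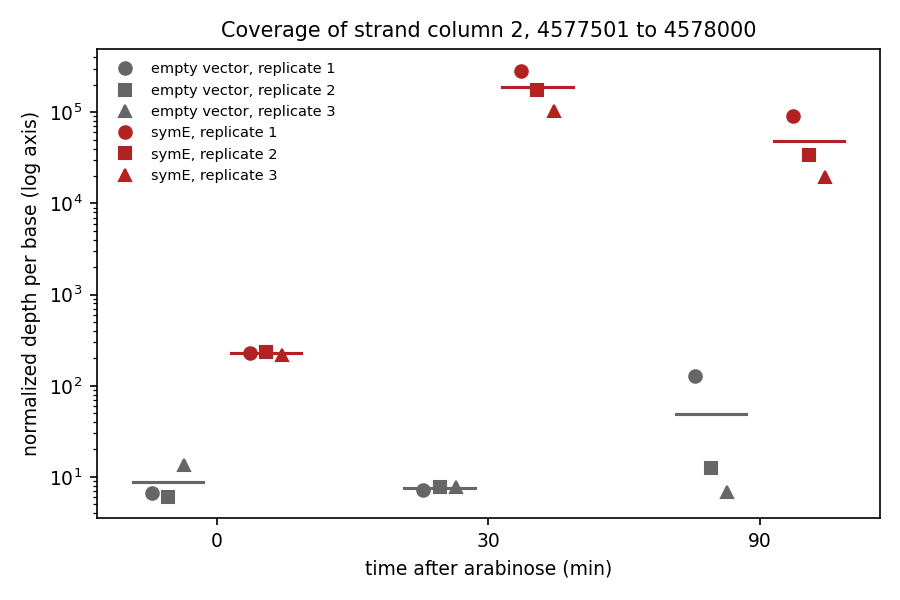
Normalized depth (log axis) of the segment from 4577501 to 4578000 on strand column 2 at 0, 30 and 90 min, for 3 empty vector (grey) and 3 symE (red) libraries per time. Depth is per 1000000000 bases of library coverage, divided by the trimmed mean factor of the library. Symbols mark replicate numbers and horizontal lines the group means; the symE libraries at 30 min lie between 103700 and 286600, and the empty vector libraries between 7.26 and 7.82.

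The arabinose genes were compared between the plasmids. Both arms received arabinose, so these values show whether the arms differed and not whether induction took place. Of the araBAD operon for arabinose use, araB (log2 -0.21, adjusted p = 0.799), araA (-0.37, adjusted p = 0.537) and araD (-0.53, adjusted p = 0.702) did not pass the test at 30 min in the authors' deposited table. The transporter genes araF (-0.83, adjusted p = 0.231), araG (-0.68, adjusted p = 0.218) and araH (-0.71, adjusted p = 0.168) did not pass either in the authors' deposited table at 30 min. The regulator gene araC was higher by 3.56 ± 0.49 at 30 min and 3.18 ± 0.57 at 90 min (log2, SE) in the authors' deposited table. Since pBAD24 carries its own araC, chromosomal and plasmid transcripts of that gene were not separated. The gene araE was in the authors' deposited table at 0.999 ± 0.39 (SE, adjusted p = 0.0706) at 30 min and rose by 1.25 ± 0.38 (SE, adjusted p = 0.00959) at 90 min. At 90 min araB (1.26), araA (0.63), araD (1.63), araF (-0.57), araG (0.05) and araH (0.12) had adjusted p from 0.179 to 0.979 in the authors' deposited table.

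Before induction the plasmids were compared to find any difference not due to arabinose. No segment of 500 nt passed between symE and empty vector at 0 min among 8491 tested with limma, with or without its trend. Of these, 21 had an unadjusted p under 0.05, far below the share of 0.05 due by chance. The groups did not overlap in 1.96% of segments, against 10% by chance if the 6 libraries were exchangeable. The test was thus strict at 0 min, and the lack of calls does not show that the plasmids were alike. With the replicate number as a block, 4 segments passed, all higher with symE. The segment from 4577501 to 4578000 already had a depth of 228 ± 9.32 with symE and 8.79 ± 4.20 with empty vector (SD, n = 3 each), with no overlap between the groups. Its log2 change of 4.63 ± 0.79 (SE) had a limma adjusted p of 0.126, so it did not pass.

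After 30 min of induction, the genes that rose with symE were mostly weakly expressed and those that fell mostly abundant. Among 4246 genes with an adjusted p in the authors' deposited table for 30 min, 392 were higher and 132 lower, with a median mean expression of 53.5 normalized counts for the higher and 1534 for the lower genes. Of the higher genes 383 rose at least 2-fold in the authors' deposited table, and of the lower genes 87 fell at least 2-fold. Besides symE, the largest increases in the authors' deposited table were ybfL (6.40 ± 1.5), yfcV (6.34 ± 0.87), a fimbrial subunit gene, a gene of the DLP12 prophage (5.90 ± 1.29), hycA (5.54 ± 1.17), a regulator of formate hydrogenlyase genes, and ygiZ (5.42 ± 1.12), all log2 with SE. Next in the authors' deposited table came intG (5.03 ± 0.92), ybcO (4.94 ± 0.90), yhiK (4.87 ± 1.29) and ybcN (4.82 ± 0.76), of which ybcO and ybcN lie in the same prophage. Apart from symE, mean expression of these genes was low, from 6.13 normalized counts for yhiK to 42.1 for ybcN. Their fold changes thus rest on few counts. The largest decrease in the authors' deposited table was that of argI, an ornithine carbamoyltransferase of arginine synthesis, by -2.22 ± 0.42 (log2, SE). It was followed in the authors' deposited table by mglC (-2.16 ± 0.28), mglA (-1.97 ± 0.56) and mglB (-1.93 ± 0.52), which encode the galactose ABC transporter, and by fiu (-1.91 ± 0.65), an iron siderophore receptor. The galactitol uptake genes gatB (-1.84 ± 0.43) and gatC (-1.82 ± 0.32), tnaA (-1.78 ± 0.47), the tryptophanase gene, purT (-1.78 ± 0.31) and ndk (-1.76 ± 0.32), both of nucleotide synthesis, completed the decreases named by rule from the authors' deposited table.

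Of 29 gene lists fixed beforehand, 5 were higher and 13 lower with symE at 30 min, relative to all other genes, by a camera test on the authors' statistics. In the SOS list of DNA damage genes, 9 of 31 passed upward, 0 downward and 22 not at all (9 and 0 adjusted over the list alone). Its list adjusted p of 0.000964 became 0.0557 with the log2 fold change as the statistic. The members that passed included yafP (2.46), recX (1.76), umuD (1.69) and umuC (1.63) at log2 values from the authors' deposited table, the last of these encoding the error-prone DNA polymerase V with umuD. Acid resistance genes were all above 0, with 4 of 14 past the test (10 adjusted over the list alone), a median log2 of 1.30 and a list adjusted p of 6.63e-05. Among them were dctR (2.04), hdeD (1.49), mdtF (1.20) and gadW (1.11) at log2 values from the authors' deposited table. The list of genes kept silent by the nucleoid protein H-NS was higher, 9 of 42 past the test (16 adjusted over the list alone; list adjusted p = 6.63e-05), with gspC at 3.16 and bglG at 2.50 in the authors' deposited table. The prophage list was higher as well, 10 of 65 past the test (10 adjusted over the list alone; list adjusted p = 1.78e-05), with essD at 3.69 and rusA at 3.50 in the authors' deposited table. That prophage call was lost, adjusted p = 0.217, once the trend of the statistic with expression level was removed. Flagella and chemotaxis genes had 5 of 48 members past the test upward (5 adjusted over the list alone), among them motA (2.72) and trg (2.21) in the authors' deposited table. Their list adjusted p of 0.0118 became 0.121 with a preset correlation of 0.05 and 0.392, in the opposite direction, with the level trend removed.

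Of the 13 lists lower at 30 min, 7 were also lower with the trend with expression level removed. Arginine synthesis genes had a median log2 of -1.18, with 6 of 13 past the test downward (9 adjusted over the list alone; list adjusted p = 0.000121). Purine and pyrimidine synthesis genes had 9 of 23 past the test downward (12 adjusted over the list alone; list adjusted p = 6.17e-06), with purM at -1.51 and purE at -1.47 in the authors' deposited table. All 9 ATP synthase genes were below 0, 6 of them past the test (8 adjusted over the list alone; list adjusted p = 5.28e-07), with atpG at -1.22 and atpH at -1.21 in the authors' deposited table. All 21 heat shock genes were below 0, 9 past the test (11 adjusted over the list alone; list adjusted p = 2.05e-07), including the chaperone genes groL (-1.72), groS (-1.68) and dnaK (-1.66) of the authors' deposited table. Branched-chain amino acid and histidine synthesis had 9 of 24 lower (12 adjusted over the list alone; list adjusted p = 8.70e-07), with hisF at -1.16 and hisH at -1.11 in the authors' deposited table. Alternative sugar uptake and use had 10 of 44 lower (13 adjusted over the list alone; list adjusted p = 6.17e-06), and iron uptake 3 of 37 (0 adjusted over the list alone; list adjusted p = 1.47e-05). Within the iron list efeO (-1.26) and feoB (-0.99) fell in the authors' deposited table.

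The other 6 lists lower at 30 min did not pass once the trend with expression level was removed. They were the TCA cycle and respiration (6 of 35 lower, 8 adjusted over the list alone; list adjusted p = 2.76e-06, then 0.0841) and aminoacyl-tRNA synthetases (2 of 23 lower, 2 adjusted over the list alone; 6.17e-06, then 0.12). The genes sucC (-1.23) and sucD (-1.13), the subunits of succinyl-CoA synthetase, led the TCA members after fumA (-1.30) in the authors' deposited table. Ribosomal protein genes had 1 of 54 past the test, rpmF at -0.87 in the authors' deposited table (0 adjusted over the list alone), with a list adjusted p of 0.000192 that became 0.608 in the opposite direction. Aromatic amino acid synthesis had 1 of 16 lower, trpB at -0.87 in the authors' deposited table (0 adjusted over the list alone; list adjusted p = 0.00797, then 0.449). Envelope stress genes (0 of 20 past the test; list adjusted p = 0.0112, then 0.815) and nucleoid-associated proteins (0 of 21; 0.0118, then 0.606) were also lost with a preset correlation of 0.05, at adjusted p of 0.0585 and 0.0636. The lists that did not pass at 30 min were methionine and sulfur assimilation (list adjusted p = 0.0772), DNA topology and replication (0.147), oxidative stress (0.173), RNA decay (0.173), Cpx envelope stress (0.193) and cold shock (0.327). Toxin-antitoxin modules (list adjusted p = 0.348), phage shock (0.507), phosphate starvation (0.507), arabinose use (0.734) and the RpoS general stress list (0.996) did not pass either. The general stress list had a median log2 of 0.16 and a test statistic below 0, and cold shock a median of -0.05 and a mean of 0.80. With the level trend removed both were higher at 30 min, with adjusted p of 0.000483 for general stress and 0.0257 for cold shock.

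In the coverage at 30 min, 573 of 8491 segments passed the limma test, 432 higher and 141 lower with symE. The direction depended on the depth of the segments tested: 32 were higher and 85 lower with a filter at depth 50, and 2303 higher and 224 lower with no filter. The groups did not overlap in 2078 of the 8491 tested segments (24.5%), against 10% by chance if the 6 libraries were exchangeable. At 0 min the share was 1.96%. After the segment at 4577501 the largest increases were on its opposite strand (log2 7.56 ± 0.93, SE), on strand column 2 from 2720501 to 2721000 (4.52 ± 0.68, SE) and from 2721501 to 2722000 (4.38 ± 0.67, SE), and on strand column 1 from 4555501 to 4556000 (4.34 ± 0.55, SE). The largest decreases lay on strand column 2 from 4476001 to 4476500 (-2.23 ± 0.64, SE) and from 2234501 to 2235000 (-2.23 ± 0.53, SE). Under a block of replicate number 2314 segments passed, 1180 higher and 1134 lower. Scaling to the total of tested segments moved the median of all segments by -0.66 (log2) and gave 2556 calls, of which 8.14% were higher against 75.4%, while a fit of the 6 libraries alone gave 2 calls. Libraries were also simulated with the residual spread of the fit over all 18 libraries, not that of 30 min alone. In these, 15% of log2 changes of 1 and 66% of those of 2 at 30 min were recovered, with 4 false calls.

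**Figure D2:**
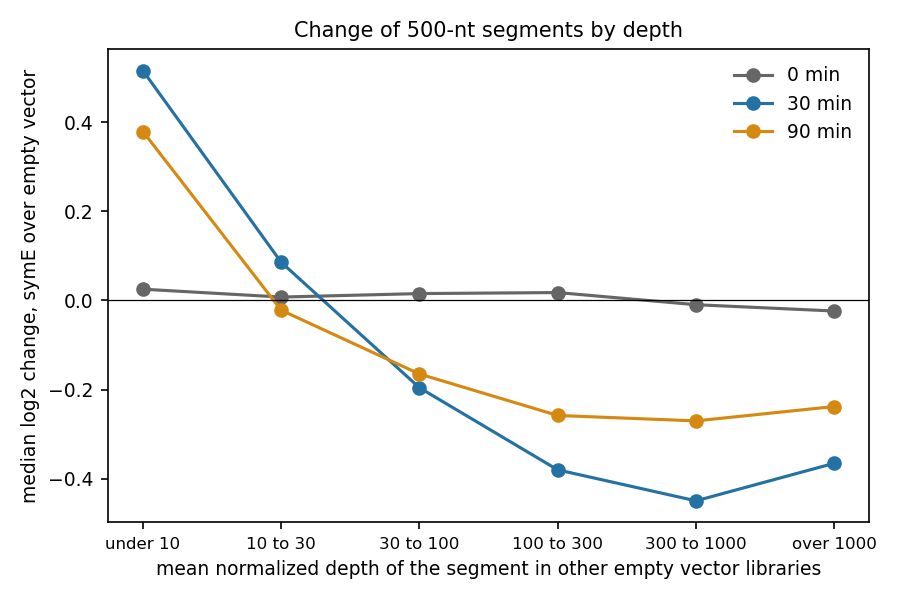
Median log2 change (symE over empty vector) of 500-nt segments at 0, 30 and 90 min, in 6 bins of normalized depth taken from empty vector libraries of another time, after trimmed mean scaling. At 30 min the median fell from 0.52 in the bin under 10 to -0.45 in the bin from 300 to 1000, and at 0 min it stayed between -0.02 and 0.03. Segments were kept by mean depth over all 18 libraries, symE at 30 and 90 min included. That filter can raise the lowest bin at these times.

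After 90 min more genes differed, and the lists of arginine synthesis and of purine and pyrimidine synthesis, lower at 30 min, were higher. Ribosomal proteins were higher as well, and their lower call at 30 min was lost with the level trend removed. The authors' deposited table for 90 min called 478 genes higher and 324 lower among 4247 with an adjusted p. After symE, the largest increases in the authors' deposited table were iraM (6.24 ± 1.39), whose product stabilizes the stress sigma factor RpoS, yhiS_1 (6.10 ± 1.21), ybfL (5.96 ± 1.24), yhiK (5.73 ± 1.06) and yibV (5.69 ± 1.19), all log2 with SE. They were followed in the authors' deposited table by yhiS_2 (5.63 ± 1.34), sfmC (5.49 ± 1.58), a fimbrial chaperone gene, yjeV (5.49 ± 1.09) and intG (5.49 ± 1.09). Apart from symE, mean expression of these genes was low, from 5.75 normalized counts for sfmC to 37.5 for yjeV. Their fold changes thus rest on few counts. The largest decreases in the authors' deposited table were all of glycerol and glycerol 3-phosphate use: glpA (-6.52 ± 1.02), glpB (-6.47 ± 0.92), glpC (-6.33 ± 0.97), glpT (-5.30 ± 0.85) and glpK (-5.22 ± 0.95). The genes glpF (-5.19 ± 1.67), glpQ (-4.63 ± 0.77) and glpD (-4.44 ± 0.79) of the same pathway came next in the authors' deposited table. They were followed in the authors' deposited table by csiD (-4.06 ± 0.71), a glutarate hydroxylase gene, and xylF (-3.69 ± 0.63), a xylose-binding protein gene.

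Of the 29 lists, 7 were higher and 2 lower at 90 min. Arginine synthesis genes were all above 0, 11 of 13 past the test (12 adjusted over the list alone), with a median log2 of 2.83 and a list adjusted p of 1.17e-13. Among them argI (4.39 ± 0.70), argF (4.39 ± 0.65), argC (4.03 ± 0.57) and argA (3.44 ± 0.55) rose in the authors' deposited table. The genes argF and argI encode near-identical enzymes, and how the authors assigned shared reads is not given in the sources used here, so their separate values are uncertain. All 54 ribosomal protein genes were above 0, 28 past the test (38 adjusted over the list alone; list adjusted p = 1.17e-13), with rplL (2.23), rpmE (2.18), rplK (2.02) and rplJ (2.01) in the authors' deposited table. All 23 purine and pyrimidine synthesis genes were above 0, 6 past the test (6 adjusted over the list alone; list adjusted p = 0.000209), with carA at 2.83, pyrD at 2.21, pyrF at 2.08 and guaB at 1.82 in the authors' deposited table. The carA gene also counts among the arginine genes. Cold shock genes had 6 of 13 higher and 1 lower (8 and 1 adjusted over the list alone; list adjusted p = 0.000904), with the RNA helicase gene deaD at 4.69 ± 0.59 in the authors' deposited table. The related genes cspI (3.64), cspG (2.28) and cspB (2.06), similar in sequence, were also higher in the authors' deposited table.

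SOS genes stayed above the other genes at 90 min, 12 of 31 past the test upward and 0 downward (12 and 1 adjusted over the list alone; list adjusted p = 0.000402). In the authors' deposited table recX (3.60), sulA (2.42), the division inhibitor, yebG (2.19) and tisB (1.96), a membrane toxin, led that list. Prophage genes had 16 of 65 higher (18 adjusted over the list alone; list adjusted p = 5.15e-06), among them kilR at 5.18 and rusA at 4.29 in the authors' deposited table. Flagella and chemotaxis genes had 12 of 48 higher (14 adjusted over the list alone; list adjusted p = 0.000243), with flgC at 3.60 and flgB at 3.47 in the authors' deposited table, and an adjusted p of 0.125 with the level trend removed. The alternative sugar uptake and use list was lower, 21 of 44 past the test (25 adjusted over the list alone; list adjusted p = 2.30e-16), with a median log2 of -2.07. General stress genes of the sigma factor RpoS were all below 0, 8 of 25 past the test (9 adjusted over the list alone; list adjusted p = 4.60e-06). In the authors' deposited table yeaH (-2.08), yeaG (-2.03), bolA (-1.91) and hchA (-1.83) led them. The other 20 lists did not pass at 90 min, with list adjusted p from 0.0836 to 0.88. With the level trend removed DNA topology and replication was higher at 90 min (adjusted p = 0.019), and a rank test called 12 lists, 8 higher and 4 lower.

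**Figure D3:**
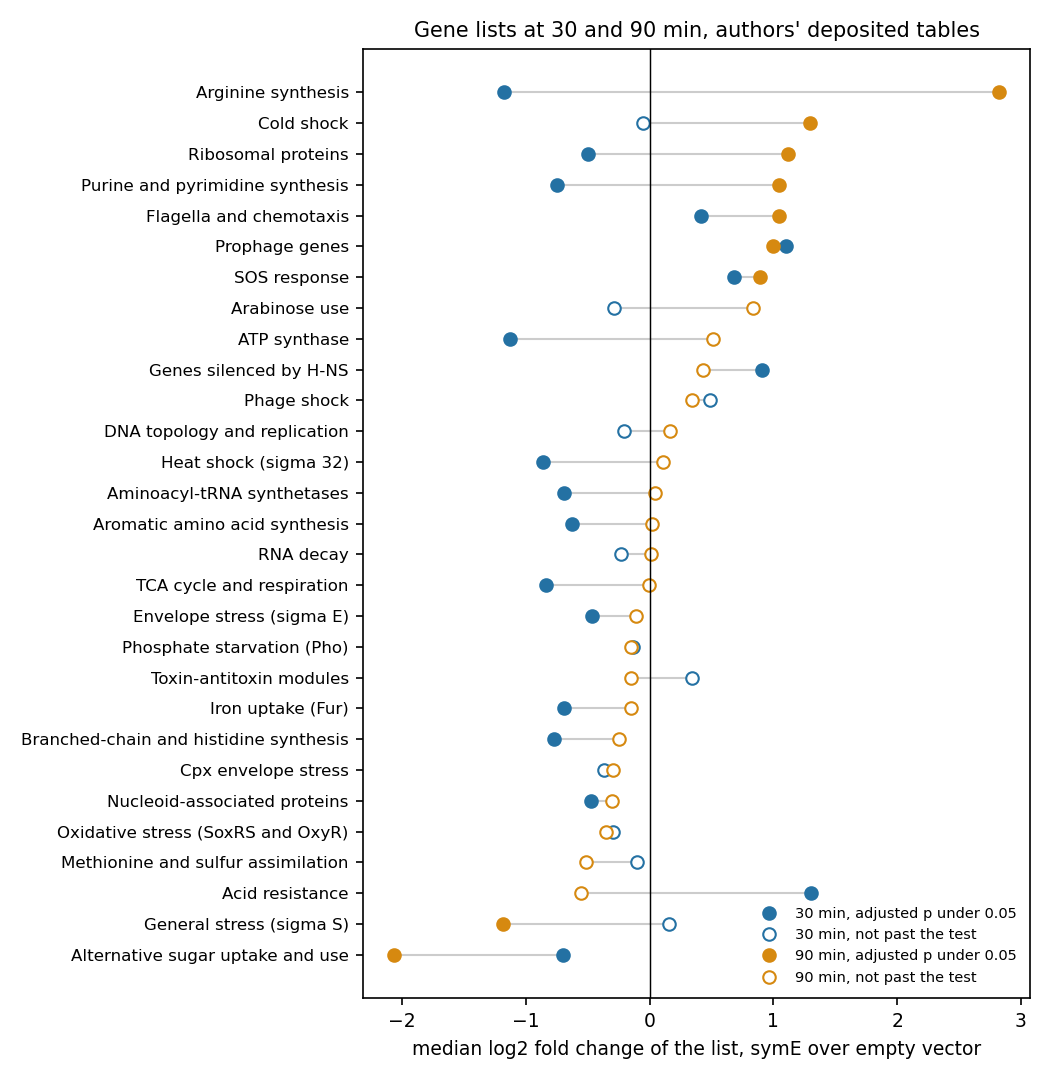
Median log2 fold change (symE over empty vector, authors' deposited tables) of 29 gene lists at 30 min (blue) and 90 min (orange), filled where the list passed the test against all other genes. Arginine synthesis moved from -1.18 to 2.83, and alternative sugar uptake and use from -0.70 to -2.07.

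In the coverage at 90 min, 1665 of 8491 segments passed the limma test, 795 higher and 870 lower. The balance depended on the segments and libraries used: 2315 were higher and 840 lower with no filter, 320 and 527 with a filter at depth 50, and 142 and 80 with the 6 libraries alone. The groups did not overlap in 2553 of the 8491 tested segments (30.1%), against 10% by chance if the 6 libraries were exchangeable and 1.96% at 0 min. Besides both strands of the segment at 4577501, the largest increases were on strand column 1 from 4391001 to 4391500 (log2 5.25 ± 0.89, SE) and on strand column 2 from 2721501 to 2722000 (5.23 ± 0.67, SE). Most of the largest decreases lay on strand column 1 between 2350501 and 2354500, the strongest at -4.87 ± 0.95 (log2, SE). At that segment, from 2353501 to 2354000, depth with symE was 4.07 ± 2.43 at 30 min and 2.97 ± 1.20 at 90 min. With empty vector it was 4.58 ± 1.21 and 250 ± 211 (SD, n = 3 each). The control thus rose between these times, with a wide spread, while symE stayed low. Under a block of replicate number 3590 segments passed, 1744 higher and 1846 lower. Under scaling to the total of tested segments 33.9% of 1642 calls were higher against 47.7%, the median of all segments moved by -0.21 (log2), and the fit of the 6 libraries alone gave 222 calls.

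Whether the effect of symE changed between times was tested directly. Between the authors' deposited tables for 30 and 90 min, 136 of 4264 genes differed by the ratio of the difference to its SE, 75 higher and 61 lower at 90 min. That SE takes the times as independent and leaves out the pairing of replicate numbers across times. The authors' deposited tables shared 232 genes higher at both times, where 44.3 are due by chance if the lists were independent, and 22 lower at both, where 10 are due. In the authors' deposited table for each time, 10 genes were lower at 30 min and higher at 90 min, where 14.8 are due by chance: argI, argG, argB, argA, argH and argC of arginine synthesis, and ndk, purF, guaA and ghxP of nucleotide supply. Only xylE, a xylose transporter gene, and ydhL were higher at 30 min and lower at 90 min in the authors' deposited table for each time, 2 genes where 30 are due by chance. Of the 29 lists, 16 differed between times by the same statistic, 13 higher and 3 lower at 90 min. The median difference (log2, 90 minus 30 min) was 3.78 for arginine synthesis (list adjusted p = 4.32e-34), 1.92 for purine and pyrimidine synthesis (3.15e-19), 1.56 for ribosomal proteins (8.56e-33) and 1.67 for ATP synthase (7.89e-11). It was -1.89 for acid resistance (list adjusted p = 2.31e-08) and -1.22 for general stress genes (1.28e-07). These list p-values take members of a list as nearly independent, by the preset correlation of 0.01. At 90 min alone, a preset of 0.05 raised the list adjusted p from 1.17e-13 to 2.95e-09 for arginine synthesis and to 4.69e-06 for ribosomal proteins. No stricter correlation was tried for the differences between times, so their list p-values may be too small. The 2 tables were normalized separately, each with a median near 0 (0.0031 at 30 min and -0.0040 at 90 min). The median difference of all genes, -0.08, therefore does not measure a shift between them.

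**Figure D4:**
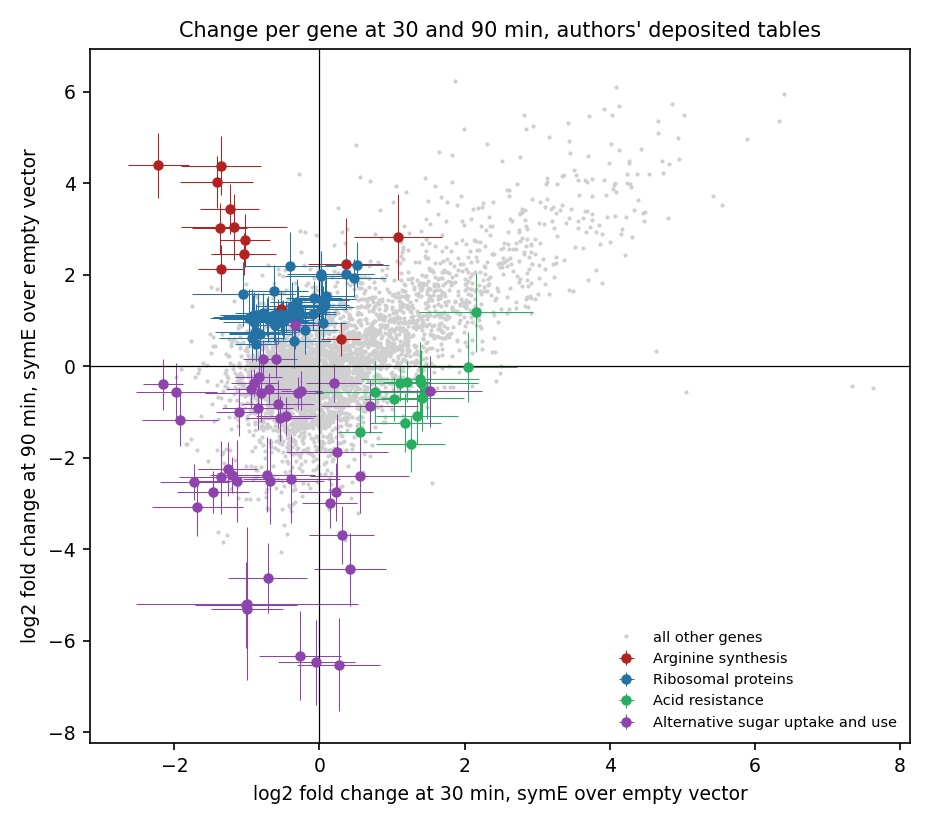
Log2 fold change (symE over empty vector) at 30 min against 90 min for each gene with a fold change at both times in the authors' deposited tables except symE, with members of 4 lists coloured and bars of 1 SE. Arginine synthesis genes such as argI lie at -2.22 and 4.39, and the glycerol 3-phosphate gene glpA, a member of the alternative sugar list, at 0.27 and -6.52.

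In the coverage, 1 segment had a larger symE effect at 30 min than at 0 min, the segment at 4577501 (log2 difference 9.67 ± 1.11, SE, limma adjusted p = 0.00254). Between 90 and 0 min 358 segments differed, 155 higher and 203 lower, and between 90 and 30 min 296, 150 higher and 146 lower. With no filter 236 were higher and 129 lower between 90 and 0 min, and 73 and 37 between 90 and 30 min, where a filter at depth 50 gave 142 and 83. Between 90 and 30 min the balance also turned without symE 90 min replicate 3 (284 higher and 396 lower) or empty vector 90 min replicate 2 (255 and 350). With the replicate number as a block the 3 counts were 351, 2132 and 1898, and with each culture as a block 618, 2661 and 2483. The largest increases from 30 to 90 min lay on strand column 2 from 4475001 to 4476500 (5.83 to 6.24) and from 288501 to 289500 (5.51 to 5.55), and the largest decrease on strand column 1 from 2353001 to 2353500 (-5.14 ± 1.18, SE). In that last segment mean depth with empty vector went from 6.58 at 30 min to 324 at 90 min, and with symE from 7.75 to 4.68. Under scaling to the total of tested segments the share of higher calls between 90 and 30 min was 93.2% against 50.7%, and between 30 and 0 min 16.7% of 6 calls against 100% of 1. Leaving out replicate 1 of every group left 0 calls between 90 and 30 min and 1 between 90 and 0 min.

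The empty vector libraries gave the response to arabinose and growth alone. At 30 min 27 segments were higher and 1 lower than at 0 min, led by segments on strand column 2 between 66501 and 70000 that rose by 8.93 to 9.37 (log2). At 90 min 97 were higher and 45 lower, with 66501 to 67000 on strand column 2 still up by 6.83 ± 0.79 and 1983501 to 1984000 up by 6.72 ± 0.79 (log2, SE). The largest decreases at 90 min lay on strand column 1 from 1361001 to 1365000, to -3.15 ± 0.47 (log2, SE), and the single decrease at 30 min from 1895501 to 1896000 on strand column 1 was by 0.98. With the replicate number as a block the counts were 298 and 582, and with each culture as a block 1026 and 1212. Under scaling to the total of tested segments 52.1% of 119 calls at 90 min were higher against 68.3% of 142.

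The question of RNA cleavage was addressed by local loss of coverage, since a break within a transcript leaves fewer fragments that span it. Each window of 50 nt was compared with the rest of its block of 1000 nt, among 58660 windows. At least 2-fold relative loss with symE was found in 1 window at 0 min, 46 at 30 min and 222 at 90 min, and at least 2-fold relative gain in 4, 98 and 471 windows. Of the losses, 1, 24 and 24 lay in the blocks from 4577001 to 4578000 that hold the induced segment. Since the rest of those blocks rose with symE, a relative loss there is no measure of lost coverage. The nearest tested segment below on strand column 2, from 4576501 to 4577000, had a log2 change of -0.17 (limma adjusted p = 0.9) at 30 min. The losses named by rule at 30 and 90 min all lay in those blocks, in windows with a mean depth of 0.041 to 6.82, with log2 changes from -14.08 to -13.72 and from -10.23 to -9.03, and so did the single loss at 0 min (-4.33 ± 0.59, SE, limma adjusted p = 0.0279). When 200 windows at 0 min were lowered by a log2 of 1 or of 2 in the symE libraries, 22.5% and 72.5% were recovered as losses. The 46 losses at 30 min fell in 10 blocks and the 222 at 90 min in 79, with up to 12 and 14 in 1 block. Blocks did not follow transcript ends, so a relative loss elsewhere can also come from a rise in the rest of its block. A called gain shared the block with 13 of the 46 and 57 of the 222 losses. Fitted with a replicate block, there were 6, 172 and 729 losses beside 4, 984 and 2214 gains. At 30 min losses outnumbered gains in replicates 2 and 3 alone (44 and 26) and without empty vector replicate 3 (17 and 9), symE replicate 2 (24 and 14) or symE replicate 1 (27 and 26).

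A narrower measure, chosen after the files were seen, asked whether a window lay below both its left and right flanks, 150 to 350 nt away. Among 37500 windows no 2-fold dip passed the limma test at 0, 30 or 90 min, and 0, 4 and 0 windows rose above both flanks. At an unadjusted p under 0.05 there were 7, 16 and 28 such dips and 6, 78 and 81 such rises. With the replicate number as a block 2 dips passed at 90 min, on strand column 1 from 1156601 to 1156650 (log2 -2.72 and -2.0 against the left and right flank) and on strand column 2 from 1928201 to 1928250 (-1.27 and -2.35). The same fit gave 3, 4 and 4 rises at 0, 30 and 90 min, so rises outnumbered dips and were present before induction. When 200 simulated breaks were placed in the symE libraries at 0 min, 53.5% of those removing 75% of spanning fragments were recovered as dips of at least 2-fold and 0% of those removing 50%, whose median log2 change at the site was -0.84. Breaks in 50% of molecules therefore lay below the 2-fold limit of this test.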

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

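The test of an even background was chosen before its result was seen, and the other tests of explanations and the counts of other splits were chosen after it. Effects of symE that differed between times by a test of the difference are given first. Between 30 and 0 min 1 segment differed, between 90 and 0 min 358, and between 90 and 30 min 296, and 136 genes of the authors' deposited table differed between 90 and 30 min. The median difference (log2, 90 minus 30 min) was above 0 for lists of arginine synthesis (3.78), purine and pyrimidine synthesis (1.92), ATP synthase (1.67), ribosomal proteins (1.56), heat shock (1.01), TCA cycle and respiration (0.86), aminoacyl-tRNA synthetases (0.78) and cold shock (0.75). It was also above 0 for aromatic amino acid synthesis (0.51), iron uptake (0.49), DNA topology and replication (0.43), branched-chain and histidine synthesis (0.39) and RNA decay (0.24). It was below 0 for acid resistance (-1.89), general stress genes (-1.22) and alternative sugar uptake and use (-1.13).

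Other splits of the libraries into groups of the same sizes were counted. For 1 call between 30 and 0 min, 9 of 100 splits gave as many, the real one included, with 160 in the highest other. That count asks for 1 call anywhere and does not test the induced segment itself, whose log2 difference was 9.67 ± 1.11 (SE) and whose depth was 103700 to 286600 with symE and 7.26 to 7.82 with empty vector at 30 min. For 358 calls between 90 and 0 min, 7 of 100 did, with 1150 in the highest other, and for 296 calls between 90 and 30 min 4 of 100, with 1632 in the highest other. Every other split with as many calls kept the real plasmid groups at the later time, so these shares neither exclude chance nor leave it open. The structure they point to is that grouping. Splits that kept the real groups at neither time, 85, 83 and 74 of them, gave at most 0, 2 and 10 calls. Among splits that part all 6 pairs, 3 of 13, 3 of 17 and 1 of 13 gave as many, with 34, 547 and 1632 in the highest. The split with 1632 calls held the real groups at both 90 and 30 min, with the plasmids exchanged at 1 of these times. It counts in the 4 of 100 but is no other grouping of the libraries. With the real groups at 90 min alone, 2 of 11 splits gave as many between 90 and 30 min, with 1530 in the highest. The blocked counts were 351, 2132 and 1898.

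For groups of 3 there are only 10 splits, too few for a share under 0.05. At 0 min all 10 splits gave the real count of 0 segments. At 30 and 90 min 1 of 10 splits, the real one, gave 573 and 1665 segments, with 0 and 15 in the highest other. For the empty vector, 1 of 10 gave 28 at 30 min and 142 at 90 min, with 0 in the highest other. For local coverage, 1 of 10 gave 4, 98 and 471 windows at 0, 30 and 90 min (gains, the larger direction), with 1, 0 and 2 in the highest other.

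At 30 min weakly covered segments were higher with symE relative to highly covered ones. The median log2 change was 0.52 in segments under a depth of 10 after trimmed mean scaling. Segments were kept by mean depth over all 18 libraries, symE at 30 and 90 min included. That filter can raise this median and steepen the slopes given below. Scaling to the total of tested segments moved the median of all segments by -0.66, so the sign for these tested segments is not settled. Without scaling, fewer positions had a depth of 0 with symE than with empty vector at 30 min. The shares were 3.36% and 8.57%, 31.8% and 38.6%, and 37.0% and 39.1% in replicates 1, 2 and 3, where symE held less total coverage. The deeper replicate 1 as the source is argued against by slopes of the change on log2 depth of -0.1799 and -0.1063 in replicates 2 and 3, below the lowest slope at 0 min, -0.0271. An even background on both strands as the whole source is argued against by 2336 segment positions with a depth under 5 on both strands in the 0 min empty vector libraries. Their added depth correlated between 30 and 90 min better on the same strand than across strands, by 0.567, 0.602 and 0.3494 (Spearman) in the 3 replicates. These positions were chosen without the filter over all libraries. Their median depth at 30 min, after trimmed mean scaling, was 0.813 with empty vector and 3.58 with symE in replicate 1. It was 0.602 and 2.725 in replicate 2, and 0.535 and 1.30 in replicate 3. A separate set held 98 positions where both strands were tested segments and depth in the 0 min empty vector libraries was under 10. There the differences in correlation were 0.452, 0.406 and 0.162, so a partial background may contribute. An effect of symE on transcription of weakly expressed regions stays open as a hypothesis.

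Arginine synthesis genes were lower at 30 min and higher at 90 min. The trend with expression level as the whole source is argued against, since the list passed at both times with the trend removed, with the larger adjusted p at 0.0221. The median difference over all genes was -0.081 beside 3.78 for the list. Each table had a median near 0 (0.0031 at 30 min and -0.0040 at 90 min). This value would thus be small with or without a shift between the separately scaled tables, and it cannot decide on one. In the coverage, scaling to the total of tested segments moved the median of the 90 minus 30 min difference by 0.45 (log2). An effect of symE, or of growth or medium that differed between the cultures, stays open and was not tested.

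Ribosomal protein genes were lower at 30 min, with 1 of 54 past the test. With the trend with expression level removed, the list had an adjusted p of 0.608 in the opposite direction, so the lower values may be part of that trend. The rise at 90 min held with the trend removed, with an adjusted p of 4.31e-17.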

How the results depend on the processing

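Replicates 2 and 3 alone, the comparison with both flanks and the alternatives for gene lists were chosen after the data were seen. Counts below are of segments for symE against empty vector at 0, 30 and 90 min (0, 573 and 1665 as reported), the differences of the symE effect between 30 and 0 (1), 90 and 0 (358) and 90 and 30 min (296), and empty vector at 30 and 90 min against 0 min (28 and 142). Median-of-ratios scaling and a pseudocount of 0.1 kept every count within 1.5 times. Scaling to the total of tested segments gave 1 at 0 min, 2556 at 30 min, 6 between 30 and 0 min and 513 between 90 and 30 min. A pseudocount of 10 gave 7 between 30 and 0 min and 230 between 90 and 0 min. With no filter there were 2527 at 30 min, 3155 at 90 min, 98 between 30 and 0 min and 110 between 90 and 30 min. A filter at depth 50, which tests fewer segments, gave 1, 117 and 847 at 0, 30 and 90 min and 209 between 90 and 0 min. Limma without trend gave 10 between 30 and 0 min. Fits of the compared groups only, with fewer libraries to estimate the spread, gave 1, 2 and 222 at 0, 30 and 90 min, 22 between 90 and 0 min, 17 between 90 and 30 min, and 51 and 6 for the empty vector. Replicates 2 and 3 only gave 2, 5 and 609 at 0, 30 and 90 min, 1 between 90 and 0 min and 0 between 90 and 30 min. What caused these differences between settings was not tested.

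With the replicate block there were 4, 2314 and 3590 calls at 0, 30 and 90 min, 351, 2132 and 1898 for the differences, and 298 and 582 for the empty vector. The pairing between plasmids that this block assumes was not established for any replicate number. The match of replicate 1 cannot be told apart from depth, and the other numbers correlated best with a different number. With the culture as the replicate block there were 618, 2661 and 2483 for the differences and 1026 and 1212 for the empty vector. Local losses with the replicate block were 6, 172 and 729.

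Leaving out each library in turn gave 0 to 0 calls at 0 min, 147 (without symE 30 min replicate 2) to 1030 (without symE 30 min replicate 3) at 30 min, and 798 (without symE 90 min replicate 2) to 2179 (without symE 90 min replicate 3) at 90 min. The ranges were 1 to 215 (without symE 30 min replicate 3) between 30 and 0 min, 7 (without symE 0 min replicate 3, or symE 90 min replicate 2) to 1047 (without symE 90 min replicate 3) between 90 and 0 min, and 71 (without empty vector 30 min replicate 3) to 680 (without symE 90 min replicate 3) between 90 and 30 min. For the empty vector they were 24 to 25 at 30 min and 43 (without its 0 min replicate 3) to 165 at 90 min. Local losses ranged from 0 to 2 (without symE 0 min replicate 1) at 0 min, 17 (without empty vector replicate 3) to 120 (without symE replicate 3) at 30 min and 24 (without empty vector replicate 3) to 514 (without symE replicate 3) at 90 min.

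Local losses (1, 46 and 222 as reported) were 4, 84 and 431 in windows of 25 nt and 0, 25 and 133 in windows of 100 nt. A block depth of at least 100 gave 2 at 0 min and 91 at 90 min, a block depth of at least 5 gave 87 at 30 min, and a pseudocount of 5 gave 2 at 0 min. Replicates 2 and 3 only gave 10 at 0 min and 43 at 90 min. The dip below both flanks gave 0, 0 and 0, and with the replicate block 0, 0 and 2 beside 3, 4 and 4 rises. The cause was not tested.

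Of 135 alternatives for 27 list calls, 121 kept the call, 12 lost it and 2 reversed. With the level trend removed, the reversed lists at 30 min were ribosomal proteins (adjusted p 0.608) and flagella and chemotaxis (0.392). With the log2 fold change as the statistic, SOS (0.0557) and flagella (0.126) did not pass at 30 min. The replicate block and leaving out libraries were not run for lists, nor DESeq2 for any result, since these need counts or gene values per library. With the level trend removed, lists that did not pass as reported were called: general stress (0.000483) and cold shock (0.0257) at 30 min and DNA topology and replication (0.019) at 90 min. The rank test called 12 lists at 90 min against 9. Of simulated breaks in 50% of molecules 0% passed as 2-fold dips, and how depth limits that test was not simulated.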

Other observations

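The tests of 6 further gene lists were chosen only after the values were seen, so their p-values are not independent evidence. Fimbrial genes of the chaperone-usher type, most of them weakly expressed, had 26 of 56 members higher at 30 min and 28 at 90 min, with yfcV at 6.34 and yadN at 4.74 at 30 min in the authors' deposited table. At 90 min all 10 genes of arginine and 4-aminobutyrate breakdown were lower, with a median log2 of -3.19, among them astC at -3.62 and gabP at -3.48 in the authors' deposited table. At 30 min 0 of these genes passed, and their median log2 was -0.02. All 6 genes of acetate uptake and the glyoxylate shunt were lower at 90 min (median log2 -2.48), with acs at -2.89 and aceA at -2.07 in the authors' deposited table, and 2 of 6 were lower at 30 min.

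Fatty acid degradation had 8 of 9 genes lower at 90 min (median log2 -2.29) and 2 of 9 at 30 min, with fadL at -2.90 and fadB at -2.69 at 90 min in the authors' deposited table. RNA polymerase genes had 3 of 5 members higher at 90 min, rpoB at 1.82, rpoA at 1.60 and rpoC at 1.53 in the authors' deposited table. Galactitol genes were lower at both times, 3 of 6 at 30 min and 4 of 6 at 90 min.

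In the empty vector libraries at 90 min, the segment from 4577501 to 4578000 on strand column 2 had a normalized depth of 127.7 in replicate 1, against 12.7 and 6.89 in replicates 2 and 3. In the authors' deposited table ykgM and ykgO, at 7.62 and 7.34 at 30 min without an adjusted p, were at -0.47 and -0.43 at 90 min.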
